A study of Mus musculus with 4 samples.

How the data were processed

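Leukaemia stem cells from the bone marrow of C57BL/6 mice were profiled by ribosome footprinting, in which nuclease digestion leaves the stretches of mRNA covered by ribosomes. There were 4 libraries, 2 labelled WT and 2 labelled KO for Rreb1. Per the labels' protocols, cell lysates were digested with micrococcal nuclease at 10 µg/ml for 30 minutes, fragments of 25 to 40 nucleotides were taken from a gel, and part of each lysate was kept as input RNA. The series calls the replicates biological; which animals they came from is not given in the sources used here, so p-values measure the spread between these libraries. The genotype field of KO replicate 2 reads Rreb2-KO, and this library was grouped with KO by its title, because the series design names no other genotype.

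The authors deposited 1 table of 16442 genes. Per the submitters' processing notes, CASAVA, HISAT2 2.1.0, featureCounts and DESeq2 were used, with no role given for each, and the genome build is hg38, a human build, although the samples and the gene symbols are mouse. The annotation is not given in the sources used here. Per the file headers, the table holds ribosome-protected fragment values, translational efficiencies and a p-value per gene. The footprint values deposited by the authors behaved as RPKM plus 1, that is, reads per kilobase of coding sequence, scaled to the library's assigned reads, with 1 added. This unit was read from the values and is not stated in the labels. The deposited translational efficiency (TE) is the ratio of the footprint value to an input RNA value with the same floor. The authors' deposited p-value column is headed as adjusted, but over 16250 genes it differed by at most 4.5e-08 from a one-sided, equal-variance test on untransformed TE without adjustment. Its counts are given only as the authors' deposited values.

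Whole reads were recovered from the RPKM steps for all 10536 genes with footprints in at least 2 libraries, within a tolerance of 0.002 reads. For 446 genes the coding length came out fractional and was multiplied, and for 10 it stayed fractional. On simulated data, 96.4% of genes came back with their exact reads and 3.5% came back too small by a common factor, which leaves ratios between libraries as they are. The assigned reads were 878068 and 656249 in WT replicates 1 and 2, and 364087 and 274183 in KO replicates 1 and 2. The shallowest library lay 3.2-fold below the deepest. A gene of 1 kilobase with a single read had an RPKM of 1.14 in WT replicate 1 and 3.65 in KO replicate 2. Input depths lay within 1.12-fold of each other. Replicates differed by more than sampling noise. The chi-square per gene of footprint reads was 5.8 between the WT libraries and 19.5 between the KO libraries, and that of input reads 3.38 and 4.66. Separate preparations of the same sample could differ in this way too, so these values do not show biological replication. Each library was counted as a replicate on the word of the series.

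The planned test assumed counts. As the table holds RPKM, the planned fallback was used: limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(RPKM + 1), with group as the only term, all 4 libraries, two-sided p-values and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are on this log2(RPKM + 1) scale, which understates changes of low genes. Genes with a CPM (recovered reads scaled by the library's assigned reads) of at least 20 in at least 2 libraries were tested, 6384 in all. RNA levels were taken as the footprint value over the TE, minus 1, and RNA and TE were fitted in the same way. Both comparisons were added after the table was seen. The per-library difference of log2 footprints and log2 RNA was used for TE, since input counts are not a column of the table, so no interaction term on counts was fitted. Python 3.11.15 was used for recovery, tests and plots.

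The main test, the rule for named genes, the first group of alternatives below and 32 gene lists were fixed before the data were examined. The lists covered the respiratory chain, succinate metabolism, mitochondria, translation, stress, stem cells, differentiation, cell cycle, signalling and markers of other cell types. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera was also run with the correlation estimated from the data, on 2 residual degrees of freedom. Run in this way it called 0 lists in footprints, in RNA and in TE. A call lost there therefore does not tell one list from another. Markers of erythroid cells and of T and NK cells had 1 tested member each and were not tested. Old gene symbols were updated through synonyms of the GRCm38.p6 annotation, which renamed 59 list genes; 14322 table symbols matched by symbol and 54 by synonym, together 87.4%. No coordinates were used. Named genes were Rreb1, the 4 subunits of complex II, the 10 genes with the largest fold change in each direction among protein-coding genes past the threshold with a mean CPM of at least 10 and no overlap between the groups, and up to 4 members of each described list with the lowest p. Any other gene is said to have been chosen after its values were seen. Of the genes the rule takes, 1 is not reported here. Where all libraries of a group had no reads, the fold is a lower bound against a floor of 3 reads over the group. With 1 to 3 reads, the ratio of pooled reads is given with its exact 95% binomial interval. Intervals and floors cover counting error only.

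The fit was tested on simulated footprint reads for the 6384 genes of the comparison, with 200 changed genes and a dispersion of 0.15. It recovered 2% of 2-fold, 26% of 4-fold, 78% of 8-fold and 90% of 16-fold changes, with 0 false calls. With no changed gene it made 0 calls and called 1 of 30 lists. The simulation gave both groups 1 dispersion, whereas the KO libraries differed from each other more than the WT libraries did.

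The alternatives fixed in advance were median-ratio and upper quartile factors, no filter, a filter at 10 CPM, limma-voom on the recovered reads, robust empirical Bayes, the replicate number as a block, each library left out in turn, protein-coding genes only, no mitochondrially encoded genes, other thresholds, pseudocounts of 0.1 and 5, camera with an estimated correlation, and fry. Alternatives added after the data were seen were TMM factors, filters at 50 CPM and at 5 RPKM of RNA, WT reads thinned to the KO depths in 20 draws, removal of genes piled up in 1 library, centring on medians and a crossed pairing.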

Results

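Ribosome footprints were measured in leukaemia stem cells, the bone marrow cells that propagate a leukaemia, from WT mice and from mice labelled as Rreb1 knockouts, with 2 libraries per group. The libraries held 878068 and 656249 assigned footprint reads in WT replicates 1 and 2, against 364087 and 274183 in KO replicates 1 and 2. Across the 6384 tested genes, footprints correlated with r = 0.94 between the WT libraries and r = 0.782 between the KO libraries, and the RNA levels implied by the deposited translational efficiencies with r = 0.997 and 0.996. Genes are not independent replicates in these correlations. The title of the series concerns translation of nuclear-encoded respiratory proteins and succinate metabolism in acute myeloid leukaemia, so footprints, RNA and their ratio, the translational efficiency (TE), were compared between the groups.

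**Figure D1:**
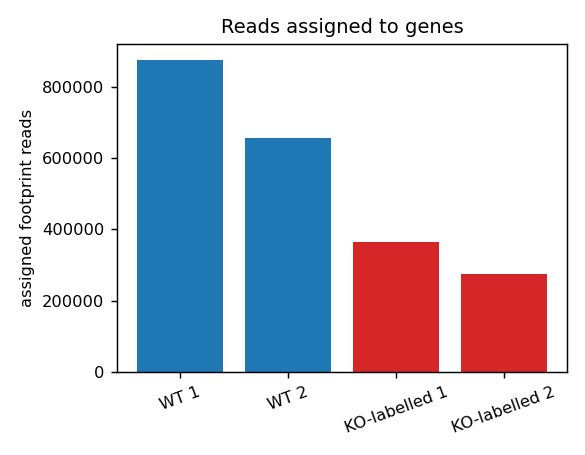
Footprint reads assigned to genes in each library, as bars, with WT in blue and KO-labelled libraries in red. WT replicate 1 is the deepest with 878068 reads, and KO replicate 2 has 274183.

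Rreb1, which encodes a zinc finger transcription factor, was not detectably lower in footprints in the libraries labelled KO. Its footprints were 14.1 and 12.8 RPKM in WT replicates 1 and 2, and 12.9 and 8.19 RPKM in KO replicates 1 and 2, from 66, 45, 25 and 12 reads. The log2 difference was -0.36 ± 0.39 (SE, n = 2 per group, limma adjusted p = 0.672), and -0.652 without KO replicate 1 and -0.06 without KO replicate 2. Its RNA was higher in the KO-labelled libraries, at 6.51 ± 0.587 RPKM against 3.29 ± 0.0508 (SD, n = 2 each), a log2 difference of 0.81 ± 0.09 (SE, limma adjusted p = 0.000282). Its TE was 1.56 ± 0.56 against 3.37 ± 0.163 (SD, n = 2 each), a log2 difference of -1.16 ± 0.39 (SE, limma adjusted p = 0.343, unadjusted p = 0.0311). The part of the gene that was removed is not given in the sources used here, and the values cover the whole coding sequence, so they do not settle whether the labels are right. The libraries are therefore called KO-labelled throughout, and each direction below rests on the labels.

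Footprints of several genes with few or no reads in WT were high in both KO-labelled libraries. Clec2m reached 251 ± 39.1 RPKM (SD, n = 2), at least 74.5-fold higher than in WT, which had no reads. Frzb, a secreted Wnt antagonist, was at least 92.9-fold higher. Cpa3, the mast cell carboxypeptidase, rose from 9.89 ± 4.97 to 605 ± 88.6 RPKM (SD, n = 2 each), a log2 difference of 5.87 ± 0.42 (SE, limma adjusted p = 0.0216). In the other direction Chil3, a chitinase-like protein of myeloid cells, fell from 33640 and 38570 RPKM in the WT libraries to 899 and 1536 RPKM, a log2 difference of -4.94 ± 0.37 (SE, limma adjusted p = 0.0216).

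In all, 67 of 6384 genes passed, 38 of them higher and 29 lower in the KO-labelled libraries (limma on log2 RPKM + 1). Other higher genes were Col6a3, a collagen chain, at least 188-fold higher, Bcat1, a branched-chain amino acid transaminase, and Faim2, each at least 19.2-fold higher, and Atp1b1, a sodium pump subunit, at 383 ± 72 RPKM against 8.34 ± 2.34 (SD, n = 2 each). Rnase12 had 1 read in each WT library, and its pooled ratio was 88.9, with an exact 95% interval of 23.8 to 748. Poll, a DNA repair polymerase, was at 885 ± 24.1 RPKM against 15.1 ± 2.54 (SD, n = 2 each). The named lower genes held Ecm1, at least 19.8-fold lower, Arhgef37, at least 11.2-fold lower, and the G1 cyclin Ccnd1, at least 9.85-fold lower. Hnmt, the histamine methyltransferase, was at least 9.71-fold lower, Gpr55 at least 9.15-fold, Dnajb4 at least 8.46-fold and Gng11 at least 6.66-fold. Fbp1, a gluconeogenic phosphatase, had 3 reads in the KO-labelled libraries, and its WT over KO ratio was 35.1 (exact 95% interval 11.9 to 171). Scin had 1 read there and a ratio of 72 (exact 95% interval 12.7 to 2860). Of the 67 genes, 32 had 3 or fewer reads in a group, and the median log2 difference of all tested genes was -0.134.

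The count rested on each library. Without WT replicate 1, and likewise without WT replicate 2, 0 genes passed limma at the adjusted threshold, with 389 and 419 at an unadjusted p under 0.05, whereas 332 passed without KO replicate 1 and 1094 without KO replicate 2, where the lone library is assumed to vary like the other group. With no filter on low genes 0 passed, with 1667 at an unadjusted p under 0.05, and limma-voom on the recovered reads called 62 genes, 43 of them among the 67.

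Nuclear-encoded subunits of the respiratory chain carry out mitochondrial oxidative phosphorylation. As a list they had a lower median in footprints and a higher one in RNA in the KO-labelled libraries, but no member passed in footprints. Over 67 tested members the median log2 difference was -0.514 in footprints, 0.472 in RNA and -1.08 in TE. Ndufa4 had 436 ± 95.9 footprint RPKM against 1657 ± 793 in WT, while its RNA rose to 152.5 ± 10.8 from 94.1 ± 1.57 RPKM (SD, n = 2 each). Cox7a2, a complex IV subunit, had a log2 difference of -1.42 ± 0.31 in footprints (SE, limma adjusted p = 0.138) and 0.53 ± 0.07 in RNA (SE, limma adjusted p = 0.00049), and Ndufc2, of complex I, of -1.48 ± 0.33 (SE, limma adjusted p = 0.138) and 0.44 ± 0.07 (SE, limma adjusted p = 0.00117).

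In footprints 0 of the 67 members passed limma over all genes and 0 adjusted over the list alone, with 18 lower and 0 higher at an unadjusted p under 0.05. In RNA 47 rose, 5 fell and 15 did not pass, and adjusted over the list alone 48 rose and 5 fell. In TE 0 passed limma over all genes, with 29 lower and 1 higher at an unadjusted p under 0.05, and 13 fell adjusted over the list alone. Camera, which compares a list with all other genes, put the list lower in footprints (adjusted p = 0.00347), higher in RNA (adjusted p = 3.06e-06) and lower in TE (adjusted p = 1.22e-08), but with an estimated correlation the adjusted p was 0.895, 0.406 and 0.914. The footprint median lay at percentile 18.4 of 10000 random lists matched on coding length and footprint level, whose median was -0.428, so it did not stand apart from genes of like length and level. The TE median lay at percentile 0.02, against a random median of -0.592. Without KO replicate 1 the footprint median was -0.309 (camera adjusted p = 0.172), and without KO replicate 2 it was -0.796 (camera adjusted p = 0.000943).

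**Figure D2:**
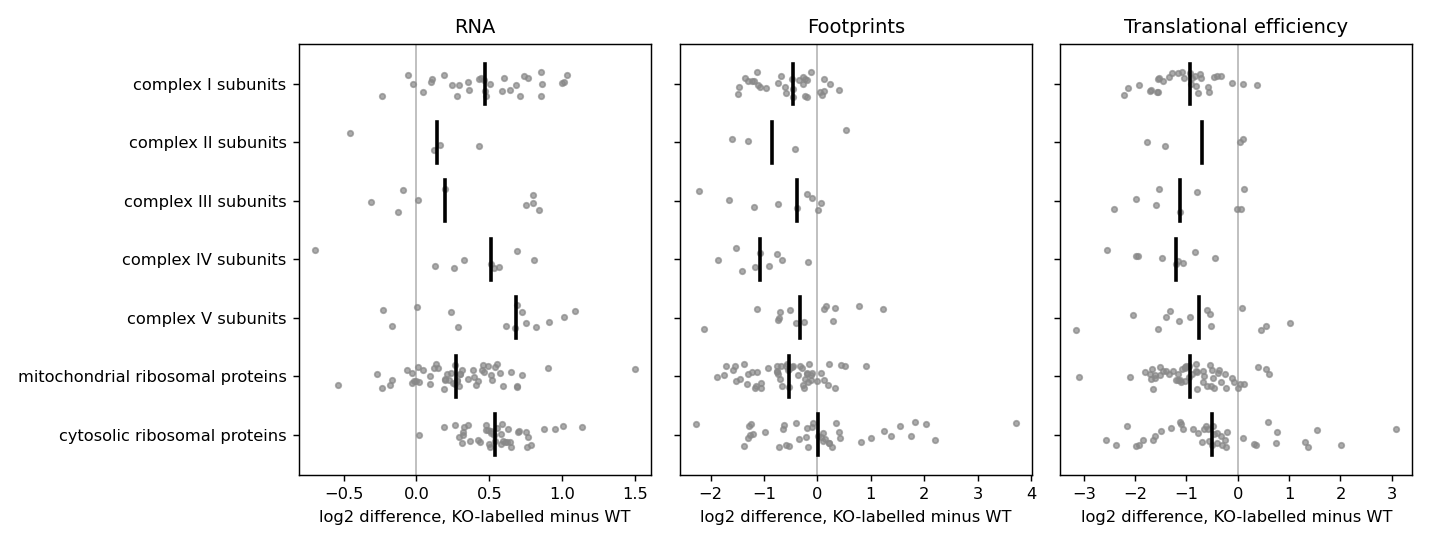
Log2 differences of KO-labelled minus WT libraries in RNA, footprints and translational efficiency for the tested members of gene lists; grey points are genes and black bars list medians. Complex I subunits have a median of 0.472 in RNA, -0.467 in footprints and -0.928 in TE.

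By complex, footprint medians were -0.467 for 31 complex I subunits (camera adjusted p = 0.021), -1.08 for 9 complex IV subunits (camera adjusted p = 0.00707), -0.378 for 9 complex III subunits (camera adjusted p = 0.22) and -0.327 for 14 complex V subunits (camera adjusted p = 0.824). With an estimated correlation the adjusted p was 0.895 for complexes I and IV. Complex IV lay at percentile 3.63 of its matched random lists in footprints and complex I at percentile 33.1. In RNA 24 complex I, 7 complex IV, 4 complex III and 11 complex V subunits rose, and 1 fell in each of these complexes. In TE complex I had a median of -0.928 and complex IV of -1.21 (camera adjusted p = 1.18e-06 and 0.000273, and adjusted p = 0.914 with an estimated correlation for both). These TE medians lay at percentiles 2.56 and 13.1 of random lists matched on coding length and footprint level, and at 21.5 and 14.7 of those matched on coding length and RNA difference, so that of complex IV did not stand apart from either. Members differed in sign: Atp5b, the catalytic subunit of ATP synthase, had 1090 ± 255 footprint RPKM against 628 ± 65.1 (SD, n = 2 each), a log2 difference of 0.78 ± 0.30 (SE, limma adjusted p = 0.276). Uqcrq, of complex III, had a TE of 1.72 ± 0.0932 against 5.18 ± 0.0459 (SD, n = 2 each; limma adjusted p = 0.289). Without KO replicate 1 the footprint medians of complexes I and IV were -0.309 and -0.672 (camera adjusted p = 0.378 and 0.113), without KO replicate 2 they were -0.788 and -1.67, and without WT replicate 2 complex I had a camera adjusted p of 0.0763.

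Complex II oxidises succinate, and its 4 subunits split. Sdhc had 146 ± 37.8 footprint RPKM in the KO-labelled libraries against 356 ± 23.5 in WT, and Sdhd 189 ± 79.4 against 554 ± 115 (SD, n = 2 each). Their log2 differences were -1.30 ± 0.31 and -1.60 ± 0.40 (SE, limma adjusted p = 0.15 and 0.165). Sdha was at 162 ± 58.9 against 208 ± 12.5 RPKM and Sdhb at 294 ± 103 against 199 ± 39.6 RPKM (SD, n = 2 each), with limma adjusted p = 0.579 and 0.505. Over all genes 0 of the 4 subunits passed limma in footprints, with 2 at an unadjusted p under 0.05, and adjusted over the list alone Sdhc and Sdhd fell. The list's footprint median was -0.859 (camera adjusted p = 0.283). RNA of Sdhc was 18.1 ± 0.202 against 16.6 ± 0.12 RPKM (SD, n = 2 each, limma adjusted p = 0.16). RNA of Sdhb rose by 0.43 and that of Sdha fell by 0.46 on the log2 scale (limma adjusted p = 0.00746 and 0.0014). RNA of Sdhd was 105.3 and 327.1 RPKM in KO replicates 1 and 2, on either side of 164.4 and 167.2 in WT (limma adjusted p = 0.76). In TE, Sdhc and Sdhd differed by -1.43 ± 0.35 and -1.76 ± 0.41 (SE, limma adjusted p = 0.298 and 0.29).

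**Figure D3:**
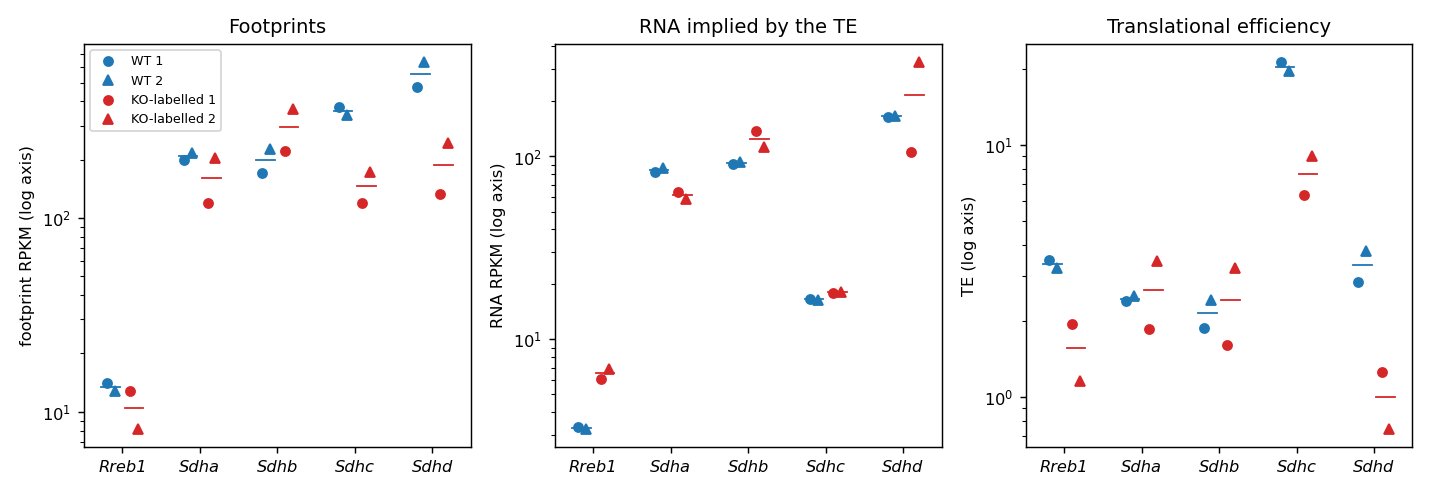
Footprint RPKM, RNA RPKM and translational efficiency of Rreb1 and the 4 complex II subunits in each library, on log axes; circles are replicate 1, triangles replicate 2, and short lines group means. Sdhc footprints average 356 RPKM in WT and 146 RPKM in the KO-labelled libraries.

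Genes of succinate and glutamine metabolism showed no detectable joint shift. Over 20 tested members the footprint median was -0.244 (camera adjusted p = 0.754), with 0 members past limma's threshold over all genes, 4 lower and 1 higher at an unadjusted p under 0.05, and 0 adjusted over the list alone. Glud1, glutamate dehydrogenase, had 105 ± 14.4 footprint RPKM against 219 ± 51.3 and Psat1, of serine synthesis, 214 ± 4.39 against 126 ± 14.7 (SD, n = 2 each), with limma adjusted p = 0.199 and 0.241. In RNA 7 members rose, 6 fell and 7 did not pass (camera adjusted p = 0.888), and Glud1 fell by 0.89 on the log2 scale (limma adjusted p = 7.39e-05). In TE the median was -0.202 (camera adjusted p = 0.733). Without WT replicate 2, KO replicate 1 or KO replicate 2 the footprint median was -0.066, 0.044 and -0.369. In TE it was -0.347, -0.104, -0.095 and -0.382 without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2.

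RNA levels, compared after the table was seen, differed widely. Of 6384 genes 3881 passed, 2112 higher and 1769 lower in the KO-labelled libraries (limma), and 1539 passed with a fold of at least 1.5 as well. Genes of myeloid differentiation were lower: of 28 tested, 18 fell, 4 rose and 6 did not pass, with a median of -0.844 (camera adjusted p = 0.000134; adjusted p = 0.406 with an estimated correlation). RNA of Lyz2, lysozyme, fell to 869 ± 71 from 5520 ± 7.99 RPKM, and that of Csf1r, the receptor of a macrophage growth factor, to 8.14 ± 0.719 from 42.05 ± 0.955 (SD, n = 2 each). Their footprint differences of -2.91 ± 0.54 and -2.74 ± 0.38 (SE) had limma adjusted p = 0.106 and 0.0642. In footprints 1 member rose and 0 fell over all genes, and 1 rose and 5 fell adjusted over the list alone, with a median of -0.401 (camera adjusted p = 0.22). The member that rose was Ltf, lactoferrin, at 118 ± 25.1 footprint RPKM against 12.8 ± 0.0317 (SD, n = 2 each; limma adjusted p = 0.0313), while its RNA did not pass (limma adjusted p = 0.691).

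Stem cell genes moved the other way. Of 23 tested, 15 rose, 1 fell and 7 did not pass in RNA, with a median of 0.383 (camera adjusted p = 0.00152; adjusted p = 0.406 with an estimated correlation). In footprints the median was 0.228, and Gata2 was among the genes that rose (camera adjusted p = 0.00347; adjusted p = 0.853 with an estimated correlation). Adjusted over the list alone, 6 rose and 1 fell. RNA of Cd34, a progenitor surface marker, rose to 50.2 ± 0.467 from 4.56 ± 0.213 RPKM (SD, n = 2 each), and its footprint difference was 2.18 ± 0.28 (SE, limma adjusted p = 0.0588). Without WT replicate 2 the footprint median was 0.097.

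Feedback and early response genes of RAS-MAPK signalling were lower in RNA. Of 14 tested, 12 fell, 1 rose and 1 did not pass, with a median of -0.677 (camera adjusted p = 0.000134; adjusted p = 0.406 with an estimated correlation), among them Fos, at 8.06 ± 1.2 against 87.2 ± 0.497 RPKM (SD, n = 2 each). Their footprint median was -1.07 (camera adjusted p = 0.0632). Genes of the cell cycle were higher in RNA: 15 of 23 G1/S genes and 14 of 24 G2/M genes rose and 0 fell, with medians of 0.33 and 0.301 (camera adjusted p = 0.00114 and 0.004; adjusted p = 0.539 with an estimated correlation for both). Top2a, a topoisomerase of dividing cells, rose to 39.7 ± 2.99 from 24 ± 1.48 RPKM of RNA (SD, n = 2 each). Their footprint medians were 0.22 and 0.196 (camera adjusted p = 0.0505 and 0.204).

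Several genes of mast cells, basophils and eosinophils were far higher. Of 7 tested, 4 rose in footprints, and 6 adjusted over the list alone, with a median of 3.47 (camera adjusted p = 4.17e-07; adjusted p = 0.84 with an estimated correlation). Besides Cpa3, Gata2 rose to 61.9 ± 23.1 from 2.25 ± 0.181 RPKM, Hdc, the histamine-forming enzyme, to 110 ± 7.15 from 14.1 ± 0.371, and the eosinophil granule gene Prg2 to 428 ± 88.6 from 39.2 ± 16.8 (SD, n = 2 each; limma adjusted p = 0.0289, 0.03 and 0.0474). Gata2 stands in the stem cell list too. In RNA 6 of the 7 rose (camera adjusted p = 0.000123, and 0.406 with an estimated correlation). With fry the list was called in RNA as well (fry adjusted p = 0.000252). Of the genes left out by the filter, chosen after their values were seen, Ear2 was lower in RNA, at 3.02 against 7.12 RPKM. Epx was higher, at 12.1 against 0.0201 RPKM.

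Some markers of other cell types differed between the groups as well. Over genes with RNA of at least 1 RPKM in 2 libraries, all members were higher in some lists. Their log2 differences in RNA were 0.62 to 4.63 (T and NK, 10 genes), 0.56 to 2.65 (erythroid, 6) and 0.71 to 3.36 (stroma, 4). B cell, megakaryocyte and macrophage genes lay on both sides of 0 (-0.72 to 1.42, -0.45 to 4.16 and -2.53 to 2.38). Genes could meet this level through the KO-labelled libraries alone. Of members left out by the filter, chosen after their values were seen, Pf4, Sparc and Cd3d differed little in RNA (log2 differences 0.19, 0.08 and 0.06). Their means were at most 1.16 RPKM in either group. Col1a1 and Lck were higher (2.29 and 1.51). Whether such cells were more frequent therefore stays open. Of 3 tested markers of stroma and endothelium, Pdgfrb rose by 3.32 ± 0.35 on the log2 scale in footprints (SE, limma adjusted p = 0.0344), and the list had a median of 1.91 (camera adjusted p = 0.00347; adjusted p = 0.895 with an estimated correlation). Markers of B cells, of megakaryocytes and platelets, and of macrophages and dendritic cells had footprint medians of -0.345, 1.98 and 0.28 (camera adjusted p = 0.824, 0.15 and 0.462). Among the macrophage and dendritic cell genes, RNA of Vcam1 fell to 5.35 ± 0.277 from 29.4 ± 0.0966 RPKM and that of Flt3, a growth factor receptor also found on progenitors, rose to 18.6 ± 1.29 from 2.76 ± 0.316 (SD, n = 2 each). Nkg7, the tested marker of T and NK cells, had 391 ± 49.8 RPKM of RNA against 14.8 ± 0.248, and Tfrc, the tested erythroid marker, 7.97 ± 0.343 against 5.09 ± 0.109 (SD, n = 2 each; limma adjusted p = 6.93e-08 and 0.000936). Of the erythroid genes left out by the filter, the globin genes, chosen after their values were seen, had higher mean RNA in the KO-labelled libraries: Hba-a1 219 against 37.6 RPKM, Hba-a2 94.9 against 14.2, Hbb-bs 112 against 19.9 and Hbb-bt 37.3 against 7.1.

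**Figure D4:**
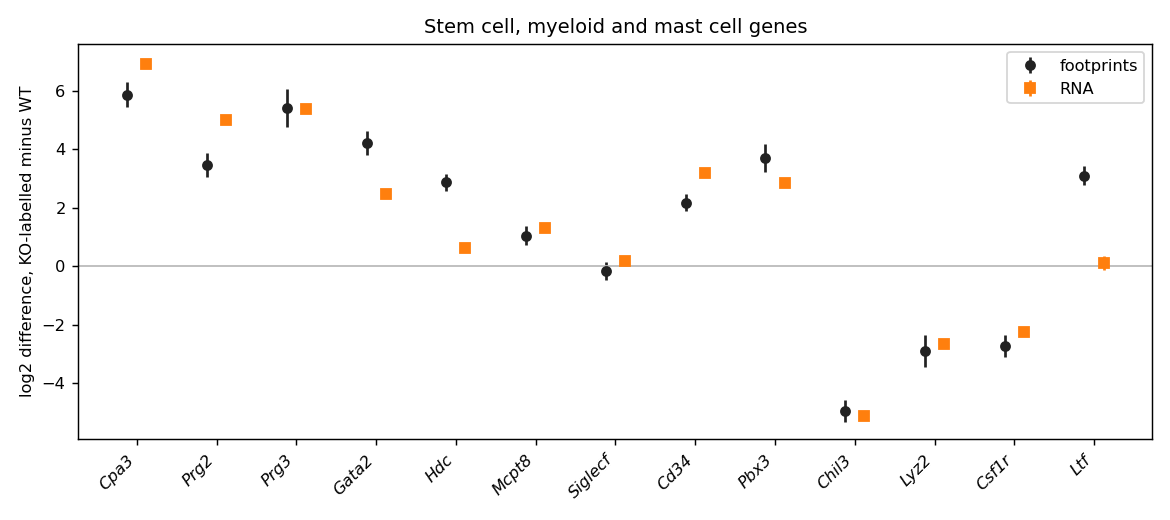
Log2 differences of KO-labelled minus WT libraries in footprints (circles) and RNA (squares) with standard errors, for mast cell, eosinophil, stem cell and myeloid genes, of which Prg3, Mcpt8 and Siglecf were chosen after their values were seen. Cpa3 differs by 5.87 in footprints and 6.92 in RNA, and Chil3 by -4.94 and -5.12.

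Translational efficiency, also compared after the table was seen, gave 0 genes past the threshold in limma, the only tool run on it, with 831 at an unadjusted p under 0.05. The lowest adjusted p was that of Poll, 0.0638, with a TE of 97 ± 4.62 against 1.8 ± 0.191 and RNA of 8.14 ± 0.186 against 7.87 ± 0.466 RPKM (SD, n = 2 each). Mitochondrial ribosomal proteins, which translate the mitochondrially encoded subunits, had a TE median of -0.928 over 54 members (camera adjusted p = 9.73e-06; adjusted p = 0.914 with an estimated correlation), and without KO replicate 1 of -0.433. Mrps14 had a TE of 2.29 ± 0.199 against 6.58 ± 0.546 (SD, n = 2 each; limma adjusted p = 0.289). The same list had a footprint median of -0.541 (camera adjusted p = 0.00965; adjusted p = 0.895 with an estimated correlation), which was -0.239 without KO replicate 1 (camera adjusted p = 0.254) and lost its call with a filter at 10 CPM and with fry too (fry adjusted p = 0.395). It lay at percentile 6.38 of matched random lists, whose median was -0.367, and the TE median at percentile 0.01. Among lists matched on coding length and RNA difference, the TE median lay at percentile 0.19, against a random median of -0.591. In RNA 33 members rose and 2 fell. Cytosolic ribosomal proteins had a TE median of -0.507 over 41 members (camera adjusted p = 0.48) and a footprint median of 0.016 (camera adjusted p = 0.216), which lay at percentile 99.98 of random lists matched on coding length and footprint level, whose median was -0.508, so it stood above genes of like length and level. In RNA 39 rose and 0 fell (camera adjusted p = 1.37e-07; adjusted p = 0.539 with an estimated correlation).

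Without KO replicate 1, 148 genes passed in TE, and without KO replicate 2, 698. The authors' deposited table lists 3432 genes with p under 0.05, of which 2609 had a lower and 823 a higher mean TE in the KO-labelled libraries. The authors' p is one-sided and unadjusted, and 3 genes remained under 0.05 after doubling and Benjamini-Hochberg adjustment. Among the 85 respiratory subunits in the authors' deposited table, 35 had p under 0.05 with lower TE and 1 with higher TE. Myeloid differentiation genes had a TE median of 0.091 (camera adjusted p = 0.0114; adjusted p = 0.914 with an estimated correlation), which was -0.029 without WT replicate 1 and -0.305 without KO replicate 2.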

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

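The filter at 50 CPM, TMM factors, thinning, removal of piled-up genes and every alternative for RNA and TE were chosen after the results were seen. In footprints, the counts of 67 changed, 38 higher and 29 lower genes became 0, 0 and 0 with no filter, 34, 17 and 17 with a filter at 10 CPM, and 187, 80 and 107 at an adjusted p under 0.1. With a filter at 50 CPM 120 changed and 66 were lower, and with a pseudocount of 5, 109 changed and 54 were lower. Filters change the number of genes tested (11151, 8108 and 3885), and the cause was not tested further. With the replicate block 32 changed, 16 higher and 16 lower, although libraries of 1 number shared little (correlation of their differences 0.022), and the block leaves 1 residual degree of freedom. Leaving out 1 library gave 0 to 1094 changed, 0 to 462 higher and 0 to 632 lower genes, with 0 without either WT library; the cause was not tested. Median-ratio, upper quartile and TMM factors gave 75, 83 and 74 changed genes and moved the median of all genes from -0.134 to 0, -0.022 and 0.018.

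The respiratory list kept its sign in all 21 alternatives and its call in 18. It lost the call with an estimated correlation and with fry (both at -0.514), and leaving out 1 library gave -0.796 to -0.309, with the call lost without KO replicate 1; the cause was not tested. Succinate and glutamine genes ranged from -0.369 to 0.044 when 1 library was left out. Of 9 lists called, 0 were called with an estimated correlation and 2 with fry. Those 2 were the stem cell list and the mast cell, basophil and eosinophil list (fry adjusted p = 0.00958 and 0.00184).

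RNA gave 6502 changed, 3762 higher and 2740 lower genes with no filter, 2452 changed and 1268 higher with a filter at 50 CPM, and 1539, 827 and 712 with a fold of at least 1.5. The replicate block gave 3480 and the crossed pairing 4390. With an estimated correlation the respiratory list in RNA (0.472) and all 16 called lists lost their calls, leaving 0. That setting called 0 lists in any measure, so it does not tell these lists apart. Fry called 21 lists in RNA, the respiratory list among them (fry adjusted p = 0.0048). Histones and mitochondrially encoded mRNAs lost their RNA calls with fry (fry adjusted p = 0.0697 and 0.15). TE gave 1 changed gene, 1 higher, with a filter at 50 CPM, with RNA of at least 5 RPKM, at an adjusted p under 0.1 and with a pseudocount of 5. Leaving out 1 library gave 0 to 698 changed, 0 to 324 higher and 0 to 374 lower genes in TE. The respiratory list in TE (-1.076) lost its call with an estimated correlation and with fry, and 0 of 7 lists kept theirs in either. Myeloid differentiation genes in TE went from 0.091 to -0.029 without WT replicate 1 and to -0.305 without KO replicate 2, within a range of -0.305 to 0.531; the cause was not tested.

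Over 26 single genes, 487 alternatives gave 378 results with the same direction and call, 109 with the same direction and no call, and 0 reversed. Over 29 other list calls in footprints, RNA or TE, where a list counts once per measure, 494 alternatives gave 429, 63 and 2. Library totals are already part of RPKM. The DESeq2 test and the edgeR settings were not run, because the deposited values are RPKM; the recovered reads were tested with limma-voom alone, which called 62 genes. On simulated reads at these depths, with 2 libraries per group, 2% of 2-fold and 26% of 4-fold changes were recovered.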

Other observations

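The tests on Y-linked genes, on cell types and on coding length were chosen only after the results were seen. The Y-linked genes, Ubap2l, Rbbp7, Epx, Prss34, Ms4a2 and Siglecf were chosen after their values were seen. Interferon response genes rose in RNA in 13 of 14 cases, with a median of 0.856 (camera adjusted p = 1.71e-05; adjusted p = 0.406 with an estimated correlation), among them Bst2, at 70.5 ± 2.52 against 23.7 ± 0.437 RPKM (SD, n = 2 each). Their footprint median was 0.336 (camera adjusted p = 0.00833; adjusted p = 0.895 with an estimated correlation), 0.232 without KO replicate 2 (camera adjusted p = 0.206) and 0.84 without KO replicate 1. Histone genes had a median of -0.714 in footprints and 0.582 in RNA over 25 members (camera adjusted p = 0.00347 and 0.00597; adjusted p = 0.895 and 0.539 with an estimated correlation), and -1.23 in TE (camera adjusted p = 2.87e-08; adjusted p = 0.914 with an estimated correlation). H4c3 had 1271 ± 189 footprint RPKM against 3370 ± 304, and its RNA rose to 18.3 ± 5 from 7.71 ± 0.552 RPKM (SD, n = 2 each). The histone footprint median was -0.235 without KO replicate 1 (camera adjusted p = 0.225), and the camera adjusted p was 0.0646 without WT replicate 2. It lay at percentile 14.7 of matched random lists, whose median was -0.526, so it did not stand apart from genes of like length and level. The TE median lay at percentile 1.72 of such lists and at percentile 6.3 of those matched on coding length and RNA difference. The RNA call was lost with fry as well (adjusted p = 0.0697). Histone mRNAs mostly lack a poly(A) tail, and how the input library was made is not given in the sources used here.

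Mitochondrially encoded mRNAs rose in RNA in 7 of 7 cases, with a median of 0.954 (camera adjusted p = 0.0358; adjusted p = 0.61 with an estimated correlation), and had medians of 0.123 in footprints and -0.706 in TE (camera adjusted p = 0.921 and 0.0476; adjusted p = 0.914 with an estimated correlation in TE). In RNA the median was 0.558 without KO replicate 2 and 0.791 without WT replicate 2 (camera adjusted p = 0.0586). The TE call was lost in 8 of 14 alternatives, among them those without WT replicate 1, KO replicate 1 or KO replicate 2 (camera adjusted p = 0.102, 0.256 and 0.109), and the TE median was -1.09 without WT replicate 1. Respiratory chain assembly factors, the tricarboxylic acid cycle and mitochondrial import and chaperones had footprint medians of -0.201, -0.352 and -0.319 (camera adjusted p = 0.517, 0.204 and 0.294). Translation factors, glycolysis, the integrated stress response, heat shock and unfolded protein response, and p53 response and apoptosis had 0.031, 0.05, -0.023, 0.04 and -0.197 (camera adjusted p = 0.21, 0.931, 0.466, 0.356 and 0.995). Ldhb, a lactate dehydrogenase of the glycolysis list, fell in RNA to 0.632 ± 0.111 from 56.2 ± 1.18 RPKM (SD, n = 2 each; limma adjusted p = 4.26e-08).

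Bcl2l1, which encodes the survival protein BCL-XL, had 261 ± 84.7 footprint RPKM against 21.45 ± 7.71, while its RNA fell to 11.85 ± 1.59 from 20.8 ± 0.558 RPKM (SD, n = 2 each; limma adjusted p = 0.0474 and 0.000466). Of the 67 genes called in footprints, 63 were called in RNA in the same direction, 2 in the opposite direction, Bcl2l1 and Ubap2l, and 2 were not called in RNA, Ltf and Poll. In 57 genes of KO replicate 1, 18 of KO replicate 2, 19 of WT replicate 1 and 0 of WT replicate 2, footprints were at 100 RPKM or more and at least 20-fold above every other library. They held at least 7.33% of the assigned reads of KO replicate 1, 1.92% of KO replicate 2 and 0.6% of WT replicate 1; these are minima, as reads could not be recovered for 9, 1 and 1 of them. Rbbp7 was at 15820 RPKM in KO replicate 1 and at most 250.9 elsewhere, with RNA of 73.8 RPKM there against a mean of 71.6.

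The list of respiratory subunits had lower medians in footprints and TE in the KO-labelled libraries, while 0 of its 67 members passed over all genes in either. Both list calls were lost with an estimated correlation (camera adjusted p = 0.895 and 0.914) and with fry (fry adjusted p = 0.395 and 0.219). WT reads thinned to the KO depths moved the list's median by -0.004, so a random loss of reads alone does not lower it. Random thinning keeps the expected RPKM of a gene, so this outcome was nearly fixed in advance. Thinning does not mimic a less complex library either, and other effects of lower depth stay open. The footprint difference lay at percentile 18.4 of lists matched on coding length and footprint level, so genes alike in both differed similarly. Lists were not matched on coding length alone, so its part cannot be told from that of level. The TE difference lay at percentile 0.02 of such lists. Among lists matched on coding length and RNA difference TE lay at percentile 1.66, but their median of -0.806 is most of the list's -1.08. Complexes I to V alone lay at percentiles 21.5, 38.9, 13.5, 14.7 and 69.9 of lists matched in this way. These percentiles take the members as independent and carry no spread between libraries. Whether part of the TE difference lies beyond coding length and a rise of RNA without footprints therefore stays open. The genotype, known only from its label, and any difference between the leukaemias or the nuclease digestions stay open and untested.

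Several genes of the mast cell, basophil and eosinophil list were higher in the KO-labelled libraries. This could come from such cells in the isolates or from the leukaemia cells themselves. Of the list's 13 genes, 46.2% had RNA at least 4-fold higher: Cpa3 and Prg2 were at 217 and 201 RPKM, Epx at 12.1 and Prss34 at 5.81, while Ms4a2 was at 0.396 against 0.422 RPKM and Siglecf at 57 against 50.1, so mature cells cannot be told apart from leukaemia cells with these genes. A lower share of leukaemia cells would raise the markers of all other cell types alike. The 3 tested B cell genes had a median RNA difference of -0.133 (interquartile range -0.428 to 0.265) against 2.47 (0.982 to 5.2) for this list. They do not decide the question, because they split: Cd79b fell by 0.72 (limma adjusted p = 0.000204), Igkc rose by 0.66 and Ighm did not pass. Whether their RNA comes from B cells was not tested. Cd79a, left out by the filter and chosen after its values were seen, was at 3.4 against 1.6 RPKM. Over genes with RNA of at least 1 RPKM in 2 libraries the medians were all above 0. They were 0.66 (B cells), 0.66 (macrophage), 1.0 (T and NK), 1.11 (megakaryocyte), 2.23 (stroma) and 2.33 (erythroid) against 2.62 for this list. A lower share of leukaemia cells therefore stays open. The gate used to isolate the cells is not given in the sources used here.

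Ddx3y and Uty, neighbours on the Y chromosome in the GRCm38.p6 annotation, had RNA of 0.0805 and 0.0847, and 0.0107 and 0.0281 RPKM in the WT libraries, against 11.9 and 13.6, and 3.57 and 3.18 RPKM in the KO-labelled libraries. Eif2s3y, the gene next to Uty, was at 21.9 and 21.5 RPKM in WT and 26.1 and 26.3 in KO-labelled libraries. Kdm5d was at 0.835 and 0.773 against 1.13 and 1.35. These values would speak against animals of different sex only if the reads come from the Y chromosome. Whether reads of similar genes elsewhere were assigned to them was not checked, so a difference of sex stays open. Another candidate explanation is that the WT leukaemia cells lost or silenced a stretch of the Y chromosome with Uty and Ddx3y, which was not tested. Either would mean that the groups differ by more than the labelled genotype.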
